A study of Mus musculus with 4 samples.

How the data were processed

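Total RNA of cultured spleen B cells was measured on Agilent 1-colour arrays with 50 ng of RNA as input and Cy3 labelling, per the labels' protocols. All 4 arrays lay on 1 slide and were scanned in 1 session, so neither could be used as a batch. The deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers, and give spot intensity as processed signal, mean signal and background signal with flags for outliers, saturation and signal well above background. Probe positions in the files are on mm9. The authors' value table gives 1 normalized intensity per probe, as whole numbers. Each of its columns holds the same set of values, with a median of 67, a 75th percentile of 1500 and 4468 probes (11.33%) at the lowest value of 15, as quantile normalization with a floor gives, but no header or label used here states how it was made. Its scale could be read from the scanner values, while the order of its genotypes could not be settled.

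Each value table column was set against each scanner array, after quantile normalization of the scanner values, over 16207 probes well above background on all 4 arrays. Of the 4 columns, 0 matched the array of their own sample best and 4 matched the array of the other genotype in the same experiment, with an SD of the log2 difference of 0.0568 to 0.201 against 0.448 to 0.582 for the array of their own sample. Scanner files were assigned to samples as recorded in the deposit, and groups were taken from the genotype in the labels. The scanner files were kept for the analysis as planned before the data were examined, so directions carry the scanner files' labels. The 2 assignments cannot both be right, and no measured value says which is. Comparisons are therefore written for arrays labelled Ackr4ko and labelled WT.

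From the scanner files, log2 of the processed signal minus each array's 75th percentile was computed. Control spots and spots flagged as outliers were left out, and the 4 spots of each probe were averaged. No spot was saturated (0). A probe was tested where at least 50% of its spots were well above background on at least 2 of the 4 arrays, which held for 20862 of 39429 probes, and a gene was represented by its brightest tested probe, giving 15963 genes. Of the probes, 28328 were named through a RefSeq accession in a GRCm38.p6 gene table, 92 through another accession, 3400 through the symbol and 222 through a synonym, and 7387 kept the array's name. That table was used only for names and for which genes lie near each other, and 12847 tested genes had a position in it. Where all probes of a gene were below background in a group, the fold is given as a lower bound: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, called its floor.

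Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no block. Replicate numbers mark the 2 experiments that the series description states, so they pair arrays, and deviations of same-experiment arrays correlated at 0.42. The fit with the experiment as a block is printed where it changed the call of a list or of a gene chosen by size or position, and as a count per list for list members. It leaves 1 residual degree of freedom per gene and, with an infinite prior, 1 variance for all genes. Gene lists (31, holding 541 genes, 438 of them tested) were written before the data were examined and tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The lists of erythroid and platelet (2 tested members), neutrophil and mast cell (3), NK and innate lymphoid (3) and sex chromosome genes (3) had fewer than 5 tested members and were not tested. The share of differing genes near Ackr4 was compared by Fisher's exact test. Fewer than 10 genes were called, so the planned replacement was used: genes at least 2-fold different in the same direction in both experiments.

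The rule for named genes was also fixed beforehand. It took Ackr4 and, in each direction, the 12 genes with the largest fold among called genes that differed the same way in both experiments. With fewer than 5 called, it took them from genes at least 2-fold different the same way in both experiments, as values, counting but not naming genes without an established symbol. From each list it took the called members or, with none called, the 2 with the smallest p. A gene that this rule names is not reported here.

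On arrays simulated from the 15963 tested genes with 200 changed genes, the fit without a block recovered 35.1% of 4-fold and 89.5% of 8-fold changes when arrays of an experiment shared 0.42 of their variance, and the blocked fit recovered 89.4% and 99.5% with 17.4 false among 166 calls on average. Alternatives covered quantile and median normalization, normexp background correction, the filter on dim probes, flagged spots, probes per gene, the variance model, the block, the value table, each array left out and the distance from Ackr4. A slide or scan block could not be run. Figures were drawn with matplotlib 3.10.9.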

Results

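Gene expression was measured in mouse B cells purified from spleen with magnetic beads and cultured for 3 days with 10 µg/mL anti-IgM, which engages the B cell receptor, and 10 µg/mL anti-CD40, which stands in for T cell help. The cells came from C57BL/6 males (WT) and from males lacking Ackr4 (Ackr4ko), an atypical chemokine receptor that takes up CCL19, CCL21 and CCL25 without G protein signalling. The labels describe 2 independent experiments with different donors, each with 1 Ackr4ko and 1 WT array, so each genotype has 2 replicates. The donors were 71 to 77 days old. All 4 arrays carried 39429 probes with 4 spots each. The 75th percentile of the processed signal was 1277 and 740 on the arrays labelled Ackr4ko and 916 and 913 on the arrays labelled WT, replicates 1 and 2. Probes well above background made up 54.9% and 49.5% of the arrays labelled Ackr4ko and 52.6% and 42.2% of those labelled WT. The array labelled WT replicate 2 stood apart, with 6.24% of its spots flagged as outliers against at most 2.12% on the others, and with a highest local background of 292 against at most 76. The number of arrays limits the precision: an exact two-sided permutation test of 2 against 2 cannot give a p below 0.333.

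The 2 kinds of deposited file disagree on which genotype each array belongs to. In each experiment the authors' value table lists the values of the array labelled Ackr4ko by its scanner file under WT, and those of the array labelled WT under Ackr4ko. Over 16207 probes the 4 columns correlated at r = 0.9984 to 0.9999 with the scanner array of the other genotype of the same experiment, and at 0.9779 to 0.9859 with the scanner array of their own label. Ackr4 itself does not decide between them. Its probes lie on chromosome 9 at 104000628 to 104000688 and 104000864 to 104000923 (mm9). Their log2 values were 2.35 and 2.44 on the array labelled Ackr4ko replicate 1, 2.74 and 2.83 on WT replicate 1, 3.32 and 3.39 on Ackr4ko replicate 2 and 4.63 and 4.69 on WT replicate 2. Both were well above background on 0 of the 4 arrays, so they check no label. Throughout, "labelled Ackr4ko" and "labelled WT" follow the scanner files. Every direction below turns round if the value table is right, while sizes, counts, the agreement between experiments and positions in the genome do not depend on it.

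**Figure D1:**
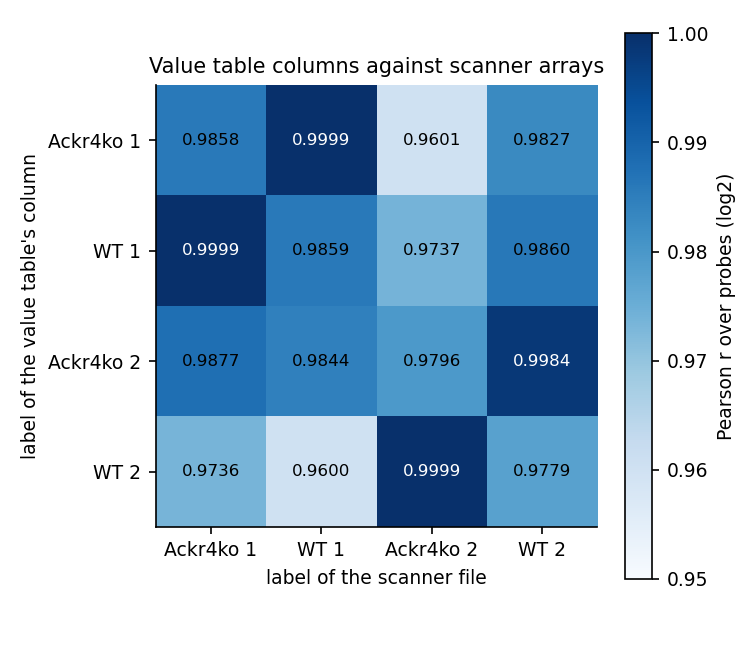
Pearson correlation, across 16207 probes on the log2 scale, of each column of the authors' value table (vertical axis, by its label) with each quantile-normalized scanner array (horizontal axis, by its label). The darkest cells, 0.9984 to 0.9999, lie at the opposite genotype of the same experiment.

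The first comparison asked which genes differ between activated B cells of the 2 genotypes. Sema3b, which encodes a secreted semaphorin, was higher on the arrays labelled Ackr4ko, with a log2 difference of 7.29 ± 0.33 (SE, n = 2 per group, limma adjusted p = 0.000109). Its mean log2 signal was 12.93 ± 0.21 (SD) on the arrays labelled Ackr4ko and 5.64 ± 0.14 on those labelled WT, where 1 of 2 arrays measured it above background. Mst1, which encodes macrophage-stimulating protein, was lower, with a log2 difference of -4.26 ± 0.33 (limma adjusted p = 0.00542), and was well above background on 0 of the 2 arrays labelled Ackr4ko, which makes it at least 11.3-fold brighter on the arrays labelled WT. Its 2 probes gave -4.26 and -4.41. Both genes lie on chromosome 9, Sema3b at 107500686 to 107500745 and Mst1 at 107987272 to 107987331 (mm9). These 2 were the genes called among 15963 tested. An unadjusted p under 0.05 was reached by 732 genes (1695 with the block described next). With independent arrays 798 would be expected by chance, but deviations of same-experiment arrays correlated at 0.42, so 798 is not a fair reference for this fit. The crossed split, with 1 array of each genotype and of each experiment in either group, gave 127. With the experiment as a block, 532 genes were called, 325 higher and 207 lower on the arrays labelled Ackr4ko, with both genes among them, but 0 were called with the block after quantile normalization (1125 at an unadjusted p under 0.05). Without a block, 24 genes were called without WT replicate 1, 122 without WT replicate 2 and 1 without either array labelled Ackr4ko, where Mst1 lost its call.

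The agreement of the 2 experiments was read from genes that differed in each of them. A difference of at least 2-fold in the same direction in both experiments was seen in 286 genes, 204 higher and 82 lower on the arrays labelled Ackr4ko, against 29.9 and 9.92 expected if the experiments were independent. In opposite directions there were 35 genes, against 34.7 expected. In 74 of the 286 genes 1 group was not above background on any array, and 249 genes (167 higher, 82 lower) were counted with those arrays at their floor. In 23 of the 286 genes, all lower, no array of 1 experiment was well above background, which leaves 263 genes (204 higher, 59 lower). The count was 116 with normexp (83 higher, 33 lower), 138 with probes above background on all 4 arrays (93 and 45) and 449 without a filter on dim probes, where more were lower (238) than higher (211). The lowest log2 signal well above background was 3.82 and 4.60 on the arrays labelled Ackr4ko and 4.31 and 5.84 on those labelled WT, replicates 1 and 2. Without the filter the median of all genes was -0.21 in experiment 1 and -0.40 in experiment 2. Lower values of dim probes, the 23 genes included, may therefore reflect background. Across genes, which are not independent replicates, the differences in the 2 experiments correlated at r = 0.339 (Spearman rho = 0.255).

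**Figure D2:**
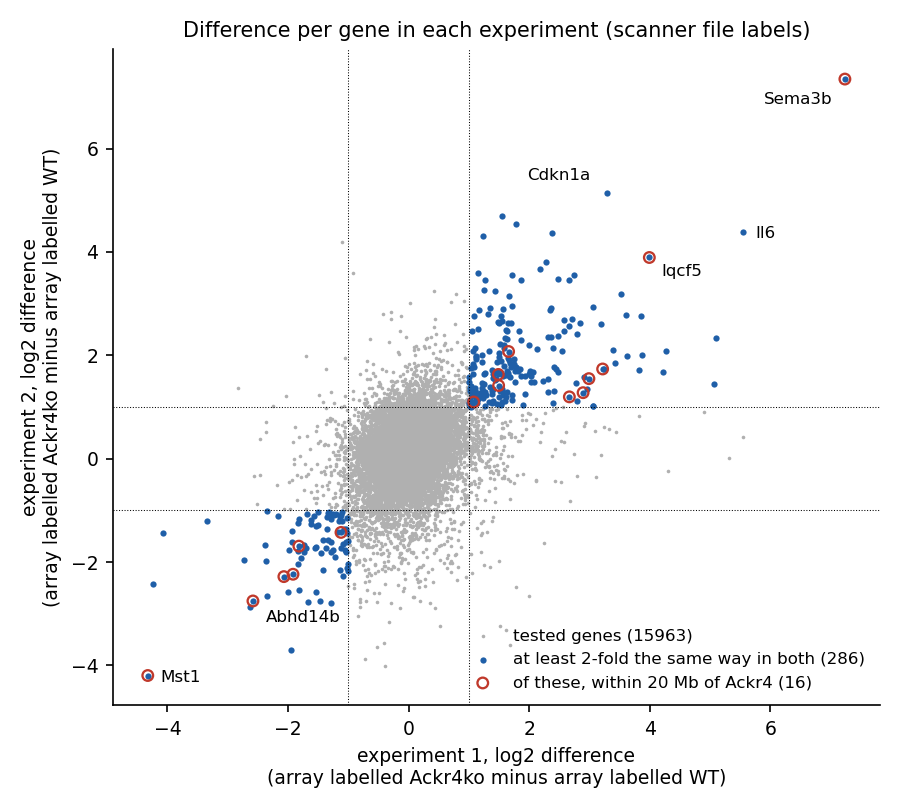
Log2 difference of each of 15963 tested genes, array labelled Ackr4ko minus array labelled WT by the scanner files, in experiment 1 (horizontal axis) and experiment 2 (vertical axis). The 286 genes in blue differed at least 2-fold (dotted lines) the same way in both, and the 16 circled in red lie within 20 Mb of Ackr4; all signs turn if the value table's labels are right.

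The largest of these differences are values, since Sema3b and Mst1 alone passed the test without a block. With the experiment as a block all 24 genes of this kind named here were called (limma adjusted p at most 9.08e-08), in a fit that gives every gene the same variance and that called 0 genes after quantile normalization. On the arrays labelled Ackr4ko, Il6, a cytokine that acts on B cells and plasma cells, was at least 16.1-fold brighter (limma adjusted p = 0.122). The cell cycle inhibitors Cdkn1a and Cdkn2a were at least 12.9-fold and 4.45-fold brighter, the stress-response factor Atf3 at least 8.57-fold and Iqcf5 at least 6.31-fold, and for all 5 genes no array labelled WT was well above background. Other genes brighter on the arrays labelled Ackr4ko, as log2 differences, were Chac1 (3.37), which degrades glutathione, Cd5l (3.31), the oxygen sensor Egln3 (3.25), the metallothionein Mt2 (3.19), the decoy receptor for interleukin 1 Il1r2 (3.18) and Apold1 (3.16), with standard errors of 0.51 to 0.80 apart from Cd5l (1.203) and Mt2 (1.501). The arrays labelled WT were brighter for Chga (-3.33), the cystatin Cst6 (-2.76), Sh3bgr (-2.75), Abhd14b (-2.67), Crisp3 (-2.50), Nin (-2.35), the metalloproteinase inhibitor Timp2 (-2.28), Gpr176 (-2.28), Pik3r3 (-2.22), the semaphorin and VEGF co-receptor Nrp1 (-2.18) and Pxylp1 (-2.17), with standard errors of 0.33 to 0.89. The 3 probes of Nin ranged from -2.35 to 0.04. Timp2, Gpr176 and Nrp1 were each well above background on 1 of 2 arrays per group and on no array of 1 experiment, so their difference there was not measured. Sema3b, Chac1, Egln3 and Apold1 were well above background on 1 of 2 arrays labelled WT, and Chga, Pik3r3 and Pxylp1 on 1 of 2 labelled Ackr4ko. In 1 experiment the difference of these genes thus rests on a value not well above background. Within these limits and those of genes given as a lower bound, the values of the 24 genes differed at least 2-fold the same way in both experiments. A further 46 genes of that kind carry no established symbol.

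Gene lists fixed before the data were examined were compared next. Of 27 lists with at least 5 tested genes, 10 passed limma's camera test with the preset correlation of 0.01, all higher on the arrays labelled Ackr4ko. With an estimated correlation none passed, and their adjusted p was 0.63 to 0.67. No member of the 27 lists was called over all genes in limma, and 23 genes in 9 lists were when adjusted over the list alone. Among the lists that passed these were immediate early (4), dendritic (4), unfolded protein response (4), p53 (2) and NF-kappaB (2) genes. The others lay in the cytokine, germinal centre, chemokine and plasma cell lists, which did not pass. The block passed 12 lists, 9 of them shared with the 10. Over all genes the block called 8 immediate early genes, 6 chemokine and migration genes, 5 genes each of glycolysis and of the p53 list, 4 each of the NF-kappaB, unfolded protein response and germinal centre lists and 3 activation genes. It called 2 each of the dendritic, survival, cytokine and marginal zone lists, 1 each of the interferon and plasma cell lists, and no member of the others of the 27. The median difference over all tested genes was 0.08, with -0.04 in experiment 1 and 0.23 in experiment 2. List medians and counts of genes higher in both experiments were not adjusted for this shift.

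Genes of glycolysis had a median log2 difference of 0.66 over 20 genes (camera adjusted p = 4.4e-06), with 14 higher in both experiments and 0 lower. The oxygen sensor Egln3, a list member that is not a glycolytic enzyme, gave 3.25, and the first glycolytic enzyme Hk2 gave 1.31. The median was 0.29 without WT replicate 1 and 1.01 without WT replicate 2. Genes of cholesterol synthesis had a median of 0.46 over 19 genes, with 14 higher in both experiments (adjusted p = 0.00112). Fdps gave 0.87. The adjusted p was 0.63 for both lists with an estimated correlation, and the cholesterol list lost its call without Ackr4ko replicate 1 (median 0.37) or WT replicate 1 (0.35). Oxidative phosphorylation did not pass, with Uqcrc2 at 0.53, Sdhc at 0.49 and a median of 0.24 that was -0.09 in experiment 1, 0.51 in experiment 2, 0.68 without Ackr4ko replicate 1 and -0.15 without Ackr4ko replicate 2.

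Genes of activated B cells made up 4 further lists that passed. Immediate early genes and feedback genes of the B cell receptor had a median of 0.63 over 18 genes, but 0.05 in experiment 1 and 1.33 in experiment 2 (adjusted p = 2.9e-05). Jun gave 1.89 and Ier3 1.78, and 4 members were called when adjusted over the list alone. The median was 1.22 without WT replicate 1, 0.38 without Ackr4ko replicate 2 and 0.29 without WT replicate 2. NF-kappaB targets had a median of 0.47, but 0.08 in experiment 1 and 0.69 in experiment 2, and 0.31 without WT replicate 2. Ier3 and Traf1 (1.27) had the smallest p, and 11 of 19 genes were higher in both experiments (adjusted p = 0.00033). Activation and costimulation genes had a median of 0.43, with the TNF family ligand Cd70 at 2.34 and the death receptor Fas at 1.25 (adjusted p = 0.00112). That median was 0.27 without WT replicate 1 and 0.71 without WT replicate 2. Survival and apoptosis genes, with Bcl2l1 at 1.40, had a median of 0.21 (adjusted p = 0.0422), but 0.33 without WT replicate 2, and missed the threshold with the block (adjusted p = 0.0571). It also missed it without Ackr4ko replicate 1 (median 0.56), Ackr4ko replicate 2 (0.14) or WT replicate 1 (0.17). With an estimated correlation the adjusted p was 0.63 for these 4 lists.

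The other lists that passed with the preset correlation held cell cycle and stress genes. Cell cycle inhibitors and p53 targets, which include Cdkn1a and Cdkn2a, had a median of 0.40, with 12 of 19 genes higher in both experiments (adjusted p = 5.2e-05, and adjusted p = 0.63 with an estimated correlation). The median was 1.02 without Ackr4ko replicate 1 and 0.11 without Ackr4ko replicate 2. G2 and M phase genes had a median of 0.45 with 17 of 19 higher in both experiments, among them Tpx2 (0.95, with its other probe at 0.17) and Bub1 (0.81) (adjusted p = 0.00112, and adjusted p = 0.67 with an estimated correlation). The G2 and M list lost its call without Ackr4ko replicate 2 (median 0.14) or WT replicate 1 (0.09), and its median was 0.72 without WT replicate 2. The S phase list did not pass, with Mcm5 at 0.36, Mcm4 at 0.37 and a median of 0.31 that ranged from -0.12 (without Ackr4ko replicate 2) to 0.52 with 1 array left out. The unfolded protein response list had a median of 0.14 (adjusted p = 0.0327, and adjusted p = 0.64 with an estimated correlation) and had its smallest p in Trib3 (2.61), a pseudokinase, and Asns (3.05), an enzyme of asparagine synthesis. It lost its call without Ackr4ko replicate 1 (median 0.15), had a median of 0.26 without WT replicate 1 and 0.03 without WT replicate 2, and turned sign with quantile normalization (-0.04).

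**Figure D3:**
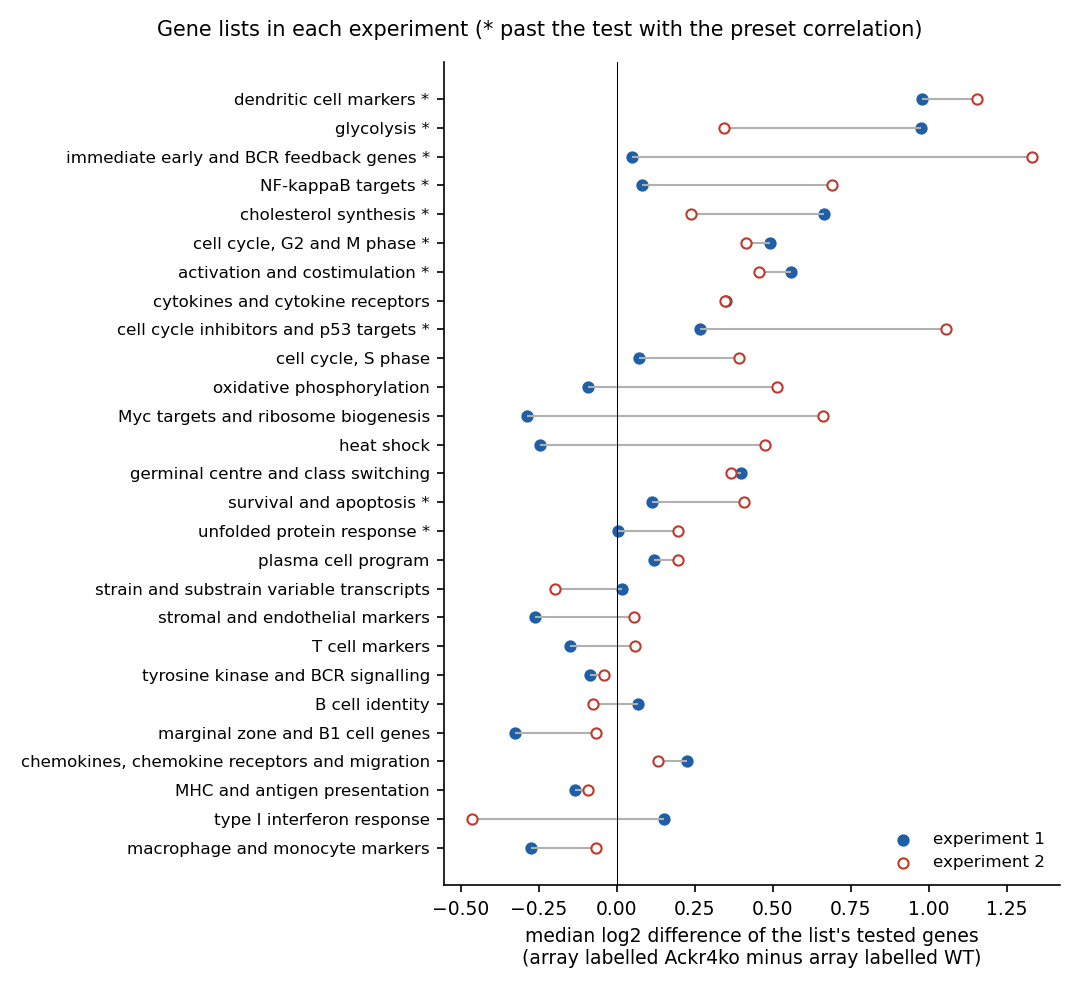
Median log2 difference of the tested genes of each of 27 lists (vertical axis), array labelled Ackr4ko minus array labelled WT by the scanner files, in experiment 1 (filled) and experiment 2 (open); an asterisk marks the 10 lists past camera with the preset correlation. Immediate early genes lie at 0.05 and 1.33, dendritic cell markers at 0.98 and 1.15, and all signs turn if the value table's labels are right.

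Markers of other spleen cells were read beside these lists. Dendritic cell markers had a median of 1.03 over 6 tested genes of 12, with 5 higher in both experiments (adjusted p = 2.9e-05, and adjusted p = 0.63 with an estimated correlation). Batf3 was at least 2.59-fold brighter and the actin-bundling protein Fscn1 at least 2.40-fold, both with no array labelled WT well above background. The sign of this median turned without a filter on dim probes (-0.28), where the median of all genes was -0.26. Macrophage and monocyte markers did not pass, with a median of -0.29, Mpeg1 at -0.78 and Cd68 at 0.51. T cell markers (-0.08, with Lat at 0.61 and Cd3g at -0.47), stromal and endothelial markers (-0.07, with Pecam1 at -1.09 and Madcam1 at 0.18) and B cell identity genes (-0.11, with Vpreb3 at 0.60 and Ralgps2 at 0.45) did not pass either. The signs of these 4 medians were not stable: with 1 array left out they ranged from -0.40 to 0.12 for macrophages, -0.26 to 0.14 for T cells, -0.24 to 0.05 for stroma and -0.30 to 0.19 for B cell identity. Lists with fewer than 5 tested members were not tested as lists, and their members were not called without the block. With the block, the erythroid and platelet list had Car2, a carbonic anhydrase, called at 1.54 (adjusted p = 0.000661) beside Slc4a1 at -0.00938, and the NK and innate lymphoid list had the chemokine gene Xcl1 called at 1.31 (adjusted p = 0.00742; -0.13 in experiment 1 and 2.76 in experiment 2) beside Prf1 at 0.34. Ly6g gave 0.72 and Elane -0.0804 in the neutrophil and mast cell list, and Eif2s3y 0.49 and Uty 0.19 among sex chromosome genes.

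The remaining lists missed the threshold without the block. With the block, 3 of them passed. Cytokines and their receptors, which include Il6 and Il1r2, had a median of 0.41 (block adjusted p = 2.2e-05), but 0.06 without WT replicate 2 and 0.28 to 0.29 without each of the other arrays. Germinal centre genes, with Basp1 at 1.93 and Plxnb2 at 1.31, had a median of 0.21 (block adjusted p = 0.00618), and 0.28 to 0.39 with 1 array left out. Interferon response genes had a median of -0.25 (block adjusted p = 0.0238), with Oasl2 at -1.51 and Ifih1 at 0.84. That median was -0.74 without Ackr4ko replicate 1, turned to 0.34 without Ackr4ko replicate 2, and was 0.15 in experiment 1 alone. With an estimated correlation and the block none of the 3 passed, each with an adjusted p = 0.63. Chemokine and migration genes had a median of -0.14 but a mean of 0.21, with the chemokines Ccl5 at 2.63 and Ccl22 at 2.34. Marginal zone and B1 cell genes had a median of -0.11, with Zbtb32 at 1.40 and Cd5 at -1.15. Plasma cell genes had a median of 0.08, with Derl3 at 1.78 and Ly6k at -1.08. The medians were -0.09 for kinases of B cell receptor signalling (Btk -0.75, Vav2 -0.54), -0.14 for antigen presentation (Ifi30 0.44, Tapbp -0.48), 0.22 for Myc targets (Pes1 -1.01, with its other probe at -0.10, and Odc1 0.77) and 0.21 for heat shock genes (Bag3 0.75, Hspb1 0.94). Transcripts known to vary between mouse strains had a median of 0.01 and a mean of -0.01, with Gbp2b at 0.85 and Ifi203 at -0.66. With 1 array left out, signs turned for chemokine genes (-0.13 to 0.10), kinases (-0.23 to 0.08), antigen presentation (-0.27 to 0.05), Myc targets (-0.19 to 0.56), heat shock (-0.09 to 0.45) and strain transcripts (-0.25 to 0.25), while the marginal zone and B1 median ranged from -0.15 to -0.0356 and that of plasma cell genes from 0.0939 to 0.20.

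The last comparison asked whether differing genes lie close to the targeted gene. Of 261 tested genes within 20 Mb of Ackr4, 16 (6.13%) differed at least 2-fold the same way in both experiments, against 238 of 12586 (1.89%) elsewhere, an odds ratio of 3.39 (1.88 to 5.73, Fisher's exact test, two-sided, p = 6.3e-05). By the scanner files' labels 10 of the 16 were higher and 6 lower on the arrays labelled Ackr4ko. Besides Sema3b, Mst1, Iqcf5, Abhd14b and Pxylp1, the following were chosen after their values were seen. Nearest to Ackr4 lay Cpne4 (at least 1.84-fold brighter on the arrays labelled Ackr4ko), followed by the phosphatase gene Dusp7 (log2 difference -1.76, with its other probe at -0.46) and Parp3 (-2.08). Farther away lay Rasgrf1 (at least 1.70-fold brighter), Plod2 (at least 2.21-fold) and, as log2 differences, Snhg5 (1.56), Rwdd2a (1.45) and Ccrl2 (1.09), which encodes a chemokine receptor-like protein. Chst2 (-1.27) was above background on no array of 1 experiment, and without such genes 15 of the 261 were of this kind (odds ratio 3.38, 1.83 to 5.81, exact p = 0.000106). With the block all genes named here were called except Ccrl2 (limma adjusted p = 0.0517). With dim groups at their floor, 13 of the 261 genes were of this kind and the odds ratio was 3.104 (1.60 to 5.52, exact p = 0.000615). With the 456 genes called with the block that have a position in the reference the odds ratio was 1.93 (1.09 to 3.19, exact p = 0.0162), and within 10 Mb it missed the threshold at 1.79 (0.837 to 3.42, exact p = 0.084). Fisher's test treats genes as independent, but Dusp7, Abhd14b, Parp3 and Iqcf5 lie together between 106277985 and 106418214 (mm9). The p-values here may therefore be too small and the intervals too narrow.

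**Figure D4:**
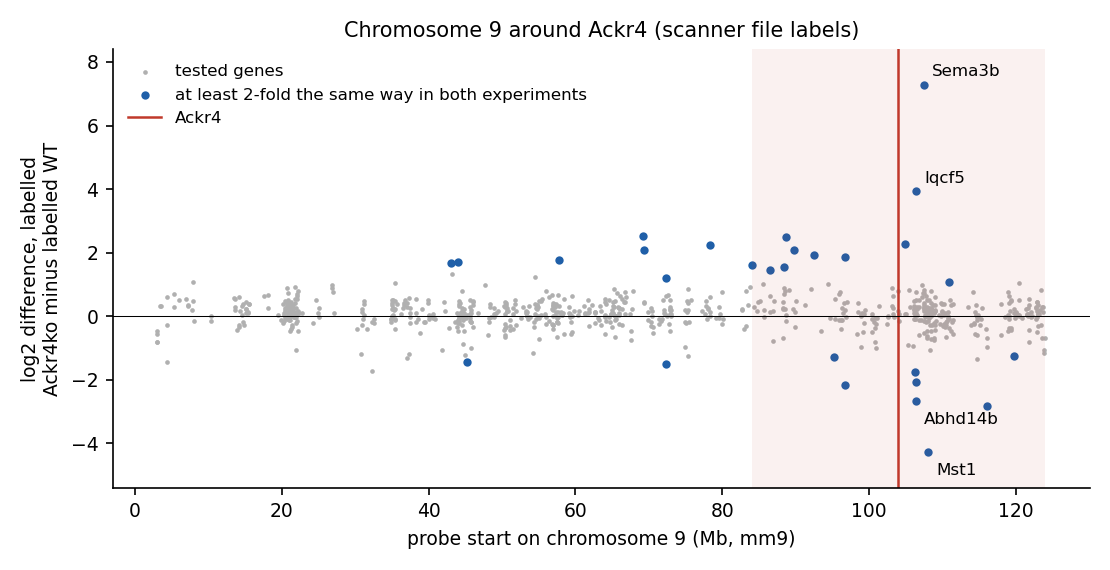
Log2 difference, arrays labelled Ackr4ko minus arrays labelled WT by the scanner files (vertical axis), of tested genes by probe position on chromosome 9 (horizontal axis, Mb, mm9), with Ackr4 as a red line, 20 Mb on either side shaded, and genes at least 2-fold different the same way in both experiments in blue. On these array positions 19 of 301 genes in the shaded window are blue (6.31%), against 1.69% elsewhere, and all signs turn if the value table's labels are right.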

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

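Settings chosen after seeing the data were the percentile over probes detected on all 4 arrays, the array positions, the block combined with another choice, dim groups at their floor, an array above background in each experiment, other filters for markers of other cells, and the value table under the scanner files' labels. Of 169 list medians recomputed, 140 kept their direction and side of the threshold, 16 missed it and 13 turned; of 1515 gene differences these were 1286, 7 and 108, and 114 newly passed. Against 2 genes called by limma (732 at an unadjusted p under 0.05), quantile normalization called 1, normexp 20 (15 higher, 5 lower), normexp with quantile normalization 1, no filter on dim probes 0 (295 under 0.05), probes above background on all 4 arrays 0 (524), each probe on its own 5, trend and robust 6, 1 with the authors' values under either labelling, an unadjusted p under 0.01 with 2-fold 237, and leaving out 1 array 1 to 122. Leaving out an array leaves 1 in that group, assumed to vary like the other group. The replicate block called 532, with trend and robust 644, with trend 657, and with all 4 arrays above background 320. With quantile normalization or the value table the block called 0 (1125 and 1460 under 0.05), where the prior had 2.61 and 2.55 degrees of freedom in place of infinitely many. A split by experiment called 0 genes (1565 under 0.05) and the crossed pairing 0 (127). Beyond the results given with it in the report, the block changed no other call of the 27 lists by camera or fry. Sema3b lost its call without the filter, where more genes were tested, and Mst1 there, with quantile normalization after either background, with the value table, and without either array labelled Ackr4ko; the cause was not tested. Genes 2-fold the same way numbered 116 and 120 with the 2 normexp settings, 449 without the filter and 138 above background on all 4 arrays, against 286; in opposite directions they numbered 9, 11, 101 and 17, against 35. The share higher was 71.3%, but 47.0% without the filter and 33.6% with the value table. Without the filter the 2 experiments correlated at 0.396 (rho 0.462), and the median of all genes was -0.26 against 0.08. The region's odds ratio kept its side of the threshold under each setting run except for genes called with the block within 10 Mb (1.79, exact p = 0.084). With camera at an estimated correlation 0 of the 27 lists passed, and with fry 0. Signs also turned for the unfolded protein response list (-0.0354 with quantile normalization, -0.0416 with normexp and quantile normalization, -0.034 with the value table under the scanner files' labels), the dendritic list (-0.28 without the filter), Madcam1 (-0.0256) and Uty (-0.11) with normexp, and, with quantile normalization and with normexp and quantile normalization, Elane (0.048 and 0.0435) and Slc4a1 (0.29 and 0.15). With 1 array left out, the log2 difference ranged from -0.021 (without WT replicate 2) to 0.38 for Madcam1, from -0.26 (without Ackr4ko replicate 1) to 1.95 for Gbp2b, from -0.11 (without WT replicate 2) to 0.50 for Uty, -0.26 to 0.0992 for Elane and -0.33 to 0.31 for Slc4a1, and, with the sign turned without Ackr4ko replicate 2, from -3.20 to 0.17 for Oasl2, -1.32 to 0.00902 for Ifi203, -0.59 to 3.22 for Xcl1, -0.0961 to 0.77 for Prf1 and -0.48 to 2.36 for Hspb1; the cause was not tested. No slide or scan block could be run, since 1 slide and 1 scan session held all arrays. Signal over background limits dim genes most on the array labelled WT replicate 2.

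The value table under its own labels turned the sign of most values, and under the scanner files' labels it kept them apart from the unfolded protein response list, so the labels and not the normalization turned them. For genes given in the report only as a lower bound, 1 group was not above background, so their differences here are not measured folds. The list medians became -0.50 for glycolysis, -0.55 for immediate early and BCR feedback genes, -0.96 for dendritic cell markers, -0.26 for cell cycle inhibitors and p53 targets, -0.37 for NF-kappaB targets, -0.32 for cholesterol synthesis, -0.39 for activation and costimulation, -0.28 for cell cycle, G2 and M phase and -0.13 for survival and apoptosis. The log2 differences became Sema3b -7.16, Il6 -4.63, Cdkn1a -4.89, Iqcf5 -3.76, Atf3 -3.56, Chac1 -3.28, Cdkn2a -3.78, Cd5l -3.16, Egln3 -3.12, Mt2 -2.997, Il1r2 -3.16, Apold1 -3.07, Mst1 4.21, Chga 3.11, Cst6 2.82, Sh3bgr 2.85, Abhd14b 2.74, Crisp3 2.56, Nin 2.41, Timp2 2.35, Gpr176 1.65, Pik3r3 2.28, Nrp1 2.21, Pxylp1 2.37, Trib3 -2.55, Asns -2.95, Ccl5 -2.44, Ccl22 -2.24, Jun -1.80, Fscn1 -1.87, Ier3 -1.70, Basp1 -1.85, Derl3 -1.77, Batf3 -3.04, Traf1 -1.13, Cd70 -2.13, Plxnb2 -1.22, Hk2 -1.27, Zbtb32 -1.28, Bcl2l1 -1.21, Fas -1.12, Car2 -1.40, Cd5 1.19, Tpx2 -0.84, Fdps -0.73, Ifih1 -0.78, Pecam1 1.15, Ly6g -0.67, Mpeg1 0.93, Ly6k 1.15, Btk 0.86, Pes1 1.105, Bag3 -0.68, Bub1 -0.72, Oasl2 1.52, Odc1 -0.61, Lat -0.49, Vpreb3 -0.49, Cd68 -0.43, Vav2 0.64, Ifi203 0.75, Sdhc -0.36, Gbp2b -0.75, Eif2s3y -0.34, Xcl1 -1.32, Ifi30 -0.32, Uqcrc2 -0.36, Tapbp 0.60, Hspb1 -0.87, Ralgps2 -0.34, Cd3g 0.50, Mcm5 -0.23, Mcm4 -0.19, Prf1 -0.26, Uty -0.0678, Madcam1 -0.73, Elane 0.13, Slc4a1 0.18, Rwdd2a -1.39, Snhg5 -1.48, Rasgrf1 -2.23, Plod2 -2.25, Chst2 0.51, Cpne4 -2.62, Dusp7 1.82, Parp3 2.02, Ccrl2 -0.69, Lca5l 1.72, Pcp4 1.57, Vegfa -2.64 and Eno2 -2.85.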

Other observations

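The lists of hypoxia and amino acid response genes, and all tests below except those of windows of the full width on other chromosomes, of the gap between experiments near Ackr4 and of the 7 lists apart in experiment 1, were chosen after the results were seen. Directions follow the scanner files' labels and turn if the value table is right. Genes of the hypoxia response had a median log2 difference of 1.16 over 19 tested genes, with 15 higher in both experiments on the arrays labelled Ackr4ko. That median was 0.37 without WT replicate 1 and 1.68 without WT replicate 2. Vegfa, a growth factor for blood vessels, gave 2.63 and the enolase gene Eno2 gave 2.93. In limma 0 members were called over all genes, 10 with the block and 7 when adjusted over the list alone, and camera gave an adjusted p = 0.148 with an estimated correlation. Genes of the amino acid response, targets of the transcription factor ATF4, had a median of 0.75 over 20 genes, with 16 higher in both experiments. They include Asns (3.05), Trib3 (2.61) and Chac1 (3.37), and 0 were called over all genes, 8 with the block and 7 when adjusted over the list alone (adjusted p = 0.0622 with an estimated correlation). The list was written after the values of these 3 were seen, and its p is adjusted over the 3 lists given here alone, so neither is independent evidence. Without Ackr4ko replicate 1 the median was 1.15. Chaperones of the endoplasmic reticulum had a median of 0.05 over 14 genes, with 4 higher and 4 lower in both experiments (adjusted p = 0.723 with an estimated correlation), and the sign turned with 1 array left out (-0.13 to 0.18). On chromosome 16, between 96380013 and 96747300 (mm9), Sh3bgr (-2.75) and Pcp4 (-1.49) were each dimmer on the arrays labelled Ackr4ko in both experiments, and Lca5l (-1.44) had no array well above background in 1 of them. Those 3 were called with the block (limma adjusted p at most 0.00203).

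The authors' value table held each array's values under the other genotype of the same experiment. If the authors' normalization changed the values, it would still leave each column closest to the array of its own label, but 0 of 4 columns were, and it could not bring them to r = 0.9984 to 0.9999 with another array. Genotype labels exchanged within each experiment in one of the 2 kinds of file would give this, and 4 of 4 columns matched the other genotype's array of the same experiment, a count that is also how the pattern was found. Whether the scanner files or the value table carry the wrong labels stays open, because Ackr4 was well above background on 0 arrays.

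Genes at least 2-fold different the same way in both experiments were more frequent within 20 Mb of Ackr4. Probe sequences mismatched by variants of another strain would, as the only cause, dim nearly all of them on one side, but 6 of the 16 lay on the less frequent side. This argues against mismatch as the cause of all 16, while for a part of them it stays open. Clustering of coregulated genes anywhere in the genome would give such shares elsewhere. On other chromosomes 0% of 10786 windows of the same width with at least 100 genes reached 6.13%. With no least number 1 of 12133 did (6.25%). At 10 Mb on either side 0.808% of 12133 windows reached the 6.75% near Ackr4, the highest at 10.3%, so some clusters do lie elsewhere. These windows were centred on each tested gene and overlap, so their number overstates how many independent stretches were compared. Of windows of 10 Mb laid side by side over the genome, none passed (one-sided Fisher's exact test). Their lowest adjusted p by that test was 0.0689 on chromosome 9, followed by 0.0722 on chromosome 11. A candidate explanation is that DNA near Ackr4 differs between the donors of the 2 genotypes, as where a targeted region is carried along from other embryonic stem cells. The median gap between experiments was 0.192 for the 16 genes and 0.433 for the other 238 of the set, and the permutation p = 0.16 (100000 permutations, two-sided) leaves this open.

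The 10 gene lists were higher on the arrays labelled Ackr4ko. The lower signal over background of the array labelled WT replicate 2 would not act in experiment 1, where 7 of the 10 lists lay above the 95th percentile of 10000 random lists. The immediate early, NF-kappaB and unfolded protein response lists did not, the highest of them at the percentile 93.8. This cannot exclude the explanation for any list, since the arrays of experiment 1 helped to choose the 10 lists. Random lists also ignore correlation within a list, estimated at 0.38 for glycolysis and 0.79 for G2 and M genes, which makes the percentiles too extreme. A lower share of B cells would raise markers of other cells alike. The 6 tested dendritic genes lay apart from 22 macrophage, T cell and stromal genes (exact two-sided permutation across genes, which are not independent replicates, p = 7.17e-05). A permutation test between the 4 lists, with genes dim in 1 group at their bound, gave permutation p = 0.0004. The filter on dim probes can keep genes bright on 1 side. Without it the mean of the dendritic genes still lay apart in the permutation test across genes (0.107 against -0.407, permutation p = 0.0382). Their median was then -0.28, against -0.38 for the other markers and -0.26 for all genes. The permutation test between the 4 lists did not pass without it (permutation p = 0.164). Above background on all 4 arrays, the permutation test across genes gave permutation p = 0.00265, and that between the lists permutation p = 0.0106. Because the result between the lists depends on the filter, a lower share of B cells stays open. So does a change in dendritic cells or in B cells that express these genes. Different activation of the cells of the 2 genotypes may account for the lists, but with an estimated correlation the lowest adjusted p = 0.627, and with 2 arrays per group this cannot be told apart from chance.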
